A study of Homo sapiens with 9 samples.

How the data were processed

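Total RNA of MCF7 cells was taken 48 h after transfection with control siRNA or with siRNA pools against RECQ1 or ESR1, and poly(A) mRNA libraries were sequenced on an Illumina HiSeq, per the labels. The 9 libraries form 3 groups of 3. The deposited table holds expected counts, the gene-level estimates of the program RSEM, for 56632 Ensembl genes and 9 libraries, per the file headers; the authors did not scale them to library size. The genome build was hg19, per the labels. The aligner, the annotation release, the program versions, the strand setting and any filter were not given in the sources used here. RSEM divides reads that match several places, so values of overlapping or antisense genes and of close paralogs such as keratins, histones, ribosomal proteins and mitochondrial genes with nuclear copies depend on that division. Of the values 88.07% were whole numbers, tested as equality after rounding; the design fixed in advance had assumed read counts, and the expected counts were rounded before the count models.

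The choices of model, threshold, gene lists, named genes and the alternative settings of the next paragraphs, unless stated, were made before the data were examined. Genes were fitted with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood with TMM scaling, the filterByExpr filter by group (minimum count 10, minimum total count 15) and 1 coefficient for each of the 3 groups, which left 16543 tested genes and 6 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over the tested genes in each of the 3 comparisons, and a gene was called at an adjusted p under 0.05. Levels are CPM on TMM-scaled libraries. Standard errors are those implied by the edgeR log2 fold change and its quasi-likelihood F statistic, with the spread estimated over all groups fitted. Nothing in the labels says whether the replicates came from separate cultures or transfections, so p-values measure the spread between these samples. Totals of 33124263 to 41982871 counts per library and a biological coefficient of variation of 0.109 set the precision.

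Gene symbols came from a table of Ensembl IDs, in which 49995 of the 56632 IDs had an entry; the 6637 others took 0.888% of the counts. Transcript length, base composition, gene type and 3' UTRs came from GENCODE release 29, built on GRCh38, matched by gene ID; no positions were taken from it. A length was found for 96.4% of the tested genes, and 13239 of the tested genes had a 3' UTR of at least 50 bases. The list members PECAM1, UHRF1 and H2BC8 were not matched.

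Named genes followed a fixed rule: RECQL and ESR1; the 8 largest increases and 8 largest decreases in each comparison with control among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, without pseudogenes, small RNAs and clone names; up to 3 called members per list and direction with the smallest adjusted p; PGR, TFF1, GREB1, GATA3, FOXA1, MYC and CCND1 whatever their call; the 6 strongest shared increases, 6 shared decreases and 4 opposite changes; and the 6 largest differences in each direction between both knockdowns. The 19 gene lists were written from general knowledge of the estrogen response, breast epithelial identity, DNA repair, cell cycle, stress, metabolism and adhesion, with markers of non-epithelial cells. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the 57 tests of 19 lists in 3 comparisons. With the estimated correlation 0, 3 and 3 lists were called after RECQ1 siRNA, after ESR1 siRNA and in the direct comparison, against 8, 7 and 9 with the preset one; with fry, which tests whether the genes of a list move on balance in a direction and does not compare them with other genes, 2, 10 and 11 were called. The luminal list contains ESR1 itself, and RBBP8, XBP1, EXO1, MYB, MSH2 and PARP1 belong to several lists.

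The alternatives set beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter on low counts (at least 1 count over all libraries), at least 1 CPM in 3 libraries, fits on the 6 libraries compared, a term for the replicate number, leaving out each library, and a threshold of at least 2-fold. After the data were seen, fits were added with a lowess trend (span 0.3, from genes above a log2 CPM of 2) of each library on transcript length, or on length and then GC content, removed through offsets, with and without RECQ1 siRNA replicate 3. Also added was the estimated correlation for all 19 lists, with the length trend removed and without each library. The effect of each is given in the closing section.

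Sequences of 7 bases from the target mRNAs were counted in the 3' UTRs of genes that fell. The expected number came from tested genes of the same class of UTR length (10 classes), UTR GC content (3) and expression (3), and 1000 random sets of matched genes gave the distribution of the largest z over the 2835 RECQL sequences with an expected count of at least 3. RECQL and ESR1 were left out of these sets. A first run of this search used a single transcript of each target; it was corrected to all transcripts, as the plan made beforehand had stated. The bounds that the slope of the estrogen genes was compared with were set after its values were seen. The slope was taken net of the shared controls, through the squared standard errors of the ESR1 siRNA effects, and its interval came from resampling genes. The interval of the ratio of the ESR1 mRNA changes came from their standard errors, taken as independent although both changes share the control libraries. The siRNA sequences were not available.

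The steps were tested on simulated counts drawn from the means and library sizes of the data, with 50 genes changed at each of 4 fold sizes. In the simulated RECQ1 siRNA comparison (16316 genes) 8, 44, 80 and 98% of genes changed 1.25-, 1.5-, 2- and 4-fold were recovered, with 8 false calls of 123; for ESR1 siRNA (16311 genes) 6, 46, 76 and 94%, with 11 of 122; and for the direct comparison (16310 genes) 4, 46, 72 and 94%, with 6 of 114. With no list changed 0 of 19 lists were called in each. Simulated genes were drawn independently of each other, so this could not show list calls that come from correlation between genes. In the RECQ1 siRNA comparison the estimated correlation was 0.0927 for the estrogen-induced list and 0.935 for ribosomal proteins. With a length trend put into a simulated RECQ1 library, removal of the trend raised recovery of 1.25-fold changes from 0 to 23% (16352 genes; false calls 0 and 2) and of 2-fold changes from 89 to 93% (16348 genes; false calls 3 and 16). That simulation used a single fixed spread for all genes, below the common estimate of the data. Its changed genes were only raised, and the slope of its trend was chosen. Its rates may therefore differ from those in the data.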

Results

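MCF7 is an estrogen receptor-positive human breast cancer cell line. Gene expression was measured by mRNA sequencing in 9 MCF7 libraries, 3 after control siRNA, 3 after pooled siRNAs against RECQ1 and 3 after pooled siRNAs against ESR1, with RNA taken at 48 h. RECQ1 is a DNA helicase of the RecQ family whose gene symbol is RECQL, and ESR1 encodes estrogen receptor alpha, the transcription factor through which estrogen acts in these cells. The deposited expected counts summed to 40092316, 39530257 and 33124263 in the control libraries. After RECQ1 siRNA they summed to 36025061, 34753792 and 39902847, and after ESR1 siRNA to 41982871, 39004060 and 35996201. After the filter on low counts, 16543 of 56632 genes were tested.

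Each siRNA pool lowered its own target in all 3 of its libraries. RECQL (ENSG00000004700) was at 2.22, 2.53 and 1.86 CPM (normalised read count, scaled to library size) after RECQ1 siRNA, against 29.7, 27.5 and 29.3 CPM after control siRNA and 28.2, 26.6 and 24.9 CPM after ESR1 siRNA. ESR1 (ENSG00000091831) was at 65.2, 72.3 and 64.4 CPM after ESR1 siRNA, against 242, 257 and 238 CPM in the controls. After RECQ1 siRNA ESR1 was at 206, 195 and 148 CPM, below each control library.

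**Figure D1:**
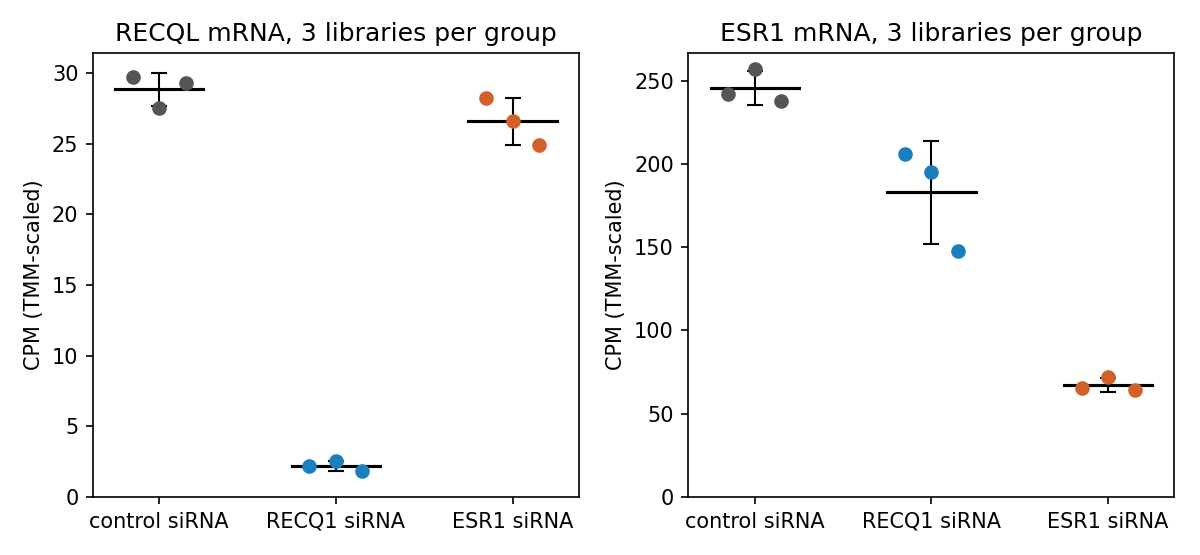
Normalised level of RECQL (left) and ESR1 (right) in each of the 9 libraries, in CPM on a linear axis from 0, by siRNA group; points are libraries, horizontal lines are means and bars are the SD (n = 3). RECQL averaged 2.20 CPM after RECQ1 siRNA against 28.8 CPM in the controls, and ESR1 averaged 67.3 CPM after ESR1 siRNA against 245 CPM.

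The comparison of RECQ1 siRNA with control siRNA shows the response of these cells to this siRNA pool, which lowered RECQL mRNA. RECQL mRNA fell 13.1-fold (log2 fold change -3.71 ± 0.11, SE, n = 3 per group, adjusted p = 8.01e-08), and 193 genes passed the test in all, 34 higher and 159 lower, so that 82.4% of the called genes fell. The changes were modest: 3 genes rose and 14 fell by at least 2-fold. Among the largest decreases were TFRC, the transferrin receptor that takes up iron, at 107 CPM against 267, and the mRNAs of secreted or surface proteins such as the matrix protein OLFML3, the plasminogen activator PLAT and the hormone STC1. Certain short sequences shared with RECQL mRNA were frequent in the 3' untranslated regions (UTRs) of the genes that fell, and their presence is given with the genes.

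The log2 fold change of TFRC was -1.32 (SE 0.10, adjusted p = 0.00023), and that of OLFML3 was -1.33 (SE 0.09, adjusted p = 0.000222). Also lower were DCBLD2, a membrane protein of the neuropilin-like family (-1.15), PLAT (-1.13), SLC16A1, the lactate and pyruvate carrier MCT1 (-1.08), PLAC1 (-1.06) and STC1 (-1.04). The SE of these was 0.09 to 0.15. Among called genes at a mean of at least 5 CPM in the higher group, the largest increases were in BRINP2, with a log2 fold change of 1.33 (SE 0.18, adjusted p = 0.00546), and SLITRK6, a neuronal transmembrane protein, with 0.94 (SE 0.11, adjusted p = 0.00241). UBE2QL1 rose with a log2 fold change of 0.88, SULF1, an enzyme that removes sulfate from heparan sulfate, with 0.86, NELL2 with 0.78, UBXN11 with 0.77, OSCP1 with 0.75 and TMEM238 with 0.73. The other genes higher by at least 2-fold lay under that level and were named after their values were seen. They were the cadherin gene CDH18, at 3.08 CPM against 1.47 (log2 fold change 1.06, SE 0.18, adjusted p = 0.0202), and the antisense RNA RNF185-AS1, at 0.446 CPM against 0 in the controls. They were called in 4 and 5 of the 9 fits that left out a library.

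ESR1 mRNA had a log2 fold change of -0.42 (SE 0.11) after RECQ1 siRNA, and its adjusted p of 0.116 did not pass the threshold, although all 3 libraries lay below all 3 controls. The call depended on the tool, the filter and the libraries. ESR1 passed with DESeq2 (-0.42, adjusted p = 0.0215) and with no filter on low counts (-0.43, adjusted p = 0.0168). The value was -0.28 (SE 0.06, adjusted p = 0.0324) without RECQ1 siRNA replicate 3, described after the gene lists. With a trend on transcript length removed from every library it was -0.32 (SE 0.05, adjusted p = 0.0056). The estrogen-responsive genes named in advance whatever their call did not pass the test. The progesterone receptor gene PGR had a log2 fold change of 0.03 (adjusted p = 0.943), TFF1 0.24 (0.413), GREB1 -0.31 (0.448), CCND1 -0.15 (0.377) and MYC -0.25 (0.0739). The luminal transcription factors GATA3 and FOXA1 had log2 fold changes of -0.19 (0.347) and 0.05 (0.741). MYC passed without RECQ1 siRNA replicate 3 (-0.23, adjusted p = 0.0326), with DESeq2 (-0.25, 0.00122) and with the length trend removed (-0.3, 0.016). It did not pass with a term for the replicate number (-0.25, 0.0874).

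Of the 52 genes of the estrogen-induced list, 7 fell, 0 rose and 45 did not pass (adjusted over the list alone, 15 lower and 2 higher). The list had a median log2 fold change of -0.15 and a list test by camera at adjusted p = 6e-06. With an estimated correlation the adjusted p was 0.318, and with fry, which does not compare the list with other genes, it was 0.00912. The median was -0.0828 without RECQ1 siRNA replicate 3 (adjusted p = 2.46e-05, and 0.425 with an estimated correlation). With the length trend removed it was -0.107 (1.17e-05, and 0.318 with an estimated correlation). The 7 were STC2 (-0.58), KRT13 (-0.82), the transcription factor gene MYB (-0.58), the carbonic anhydrase gene CA12 (-0.41), CHPT1 (-0.46), the zinc transporter gene SLC39A6 (-0.46) and PDZK1 (-0.50). Of these CA12, CHPT1, SLC39A6 and PDZK1 were named after their values were seen. STC2 and KRT13 were the members called in each of the 9 fits that left out a library. All 7 also fell after ESR1 siRNA, as did 46 of all 52 members, in a comparison with the same control libraries. The estrogen-repressed list had 0 of 17 members called (adjusted over the list alone, 1 higher and 3 lower), a median of -0.06 and adjusted p = 0.814.

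Single members passed in several other lists. In the G1/S list of 39 genes the uracil-DNA glycosylase gene UNG fell (log2 fold change -0.85, adjusted p = 0.00075), while the list as a whole had a median near 0 and adjusted p = 0.705. In the list of RecQ helicases and their partners 1 of 14 passed. XRCC6, which encodes the end-joining protein Ku70, fell (-0.52, adjusted p = 0.0112; list adjusted p = 0.293). Of 25 p53 targets SESN2, a stress-response gene, fell (-0.33, adjusted p = 0.0364). The p53 list had adjusted p = 0.241, and its median of 0.00463 and its test differed in sign. Without RECQ1 siRNA replicate 3 the list adjusted p was 0.0439, towards lower, and 0.425 with an estimated correlation. Of 23 cholesterol synthesis genes CYP51A1 fell (-0.35, adjusted p = 0.0305; list adjusted p = 0.586). Adjusted over the list alone, the number lower was 1, 1, 2 and 1 in these 4 lists, and 1 p53 target was higher. None of the 34 homologous recombination and DNA damage response genes was called, nor adjusted over the list alone (list adjusted p = 0.238). MYB was also the sole called member of the 23 luminal identity genes (adjusted over the list alone, 2 lower), whose median of 0.0163 and test direction differed in sign (adjusted p = 0.652).

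In the basal and mesenchymal list KRT17, a basal keratin, rose (0.68) and CAV1, which encodes caveolin-1, fell (-0.74) among 16 tested genes (adjusted over the list alone, 2 higher and 4 lower). The list test gave adjusted p = 0.0175 towards lower, adjusted p = 0.355 with an estimated correlation and adjusted p = 0.069 with the length trend removed. Without control replicate 2 or RECQ1 siRNA replicate 2 it was 0.0603 or 0.0804. The fry adjusted p with all libraries was 0.0311. In the adhesion, migration and TGF-beta list 1 of 28 genes fell, the ligand gene TGFB2 (-0.62; adjusted over the list alone, 3 lower and 1 higher). The list test gave adjusted p = 0.0153 towards lower, adjusted p = 0.601 with an estimated correlation and adjusted p = 0.676 without RECQ1 siRNA replicate 3. Of the lists with no called member, 5 were higher by camera: the mitochondrially encoded genes (median 0.50, adjusted p = 5.68e-06), nuclear oxidative phosphorylation genes (0.20, 0.000332), ribosomal proteins (0.16, 0.00144), histones (0.19, 0.0197; adjusted over the list alone, 1 higher) and G2/M genes (0.05, 0.0153). With an estimated correlation their adjusted p values were 0.589, 0.767, 0.789, 0.601 and 0.601. The G2/M list was not called without control replicate 3 (0.0515) or RECQ1 siRNA replicate 1 (0.0993), nor the histones without control replicate 1 (0.0622) or RECQ1 siRNA replicates 2 (0.0662) or 3 (0.119). The mitochondrially encoded median was 0.791 without control replicate 1 and 0.329 without control replicate 2. The G2/M median was 0.0823 without control replicate 1 and 0.0825 without RECQ1 siRNA replicate 3. The oxidative phosphorylation and ribosomal medians were 0.302 and 0.263 without RECQ1 siRNA replicate 1, and without replicate 3 these lists were not called. Adjusted over the list alone 0 members were called in the other 4 of these lists. The interferon, unfolded protein, hypoxia and non-epithelial lists also had 0 called members (adjusted over the list alone, 0, 0, 0 and 1 higher), with adjusted p of 0.47, 0.224, 0.759 and 0.586.

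RECQ1 siRNA replicate 3 differed from the other libraries of its group along transcript length. Its deviation from the mean of the other 2 libraries correlated across genes with transcript length at Spearman rho = -0.74, with a median log2 deviation of 0.48 for 472 genes under 1000 bases and -0.53 for 933 genes over 8000 bases. Genes are not independent replicates. Control libraries had rho from -0.42 to 0.34 and ESR1 siRNA libraries from -0.29 to 0.52. The lowest value of each group was that of replicate 3. With transcript GC content, replicate 3 correlated at 0.39 (control), 0.31 (RECQ1 siRNA) and 0.73 (ESR1 siRNA). Each other library had a negative value there (-0.47 to -0.14). The lists with the shortest transcripts were the histones and the mitochondrially encoded genes (median 870 bases each), ribosomal proteins (1344) and oxidative phosphorylation (1533), against 3029 for all tested genes with a length. Without RECQ1 siRNA replicate 3 the ribosomal protein median was -0.02 (adjusted p = 0.644, test towards lower), and the oxidative phosphorylation median was 0.03 (0.302) and the histone median 0.13 (0.119). The mitochondrially encoded median was 0.48 (3.03e-05, and 0.615 with an estimated correlation). With the length trend removed from every library the oxidative phosphorylation list stayed higher (median 0.0974, adjusted p = 0.0065), as did the mitochondrially encoded list (0.38, 0.00678). Neither passed with an estimated correlation (0.557 and 0.756). The ribosomal (0.06, 0.337) and histone (0.0434, 0.662) lists did not pass at the preset correlation. The mitochondrial share of counts was 1.28 to 2.34% in controls, 2.35 to 2.51% after RECQ1 siRNA and 1.66 to 3.09% after ESR1 siRNA.

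**Figure D2:**
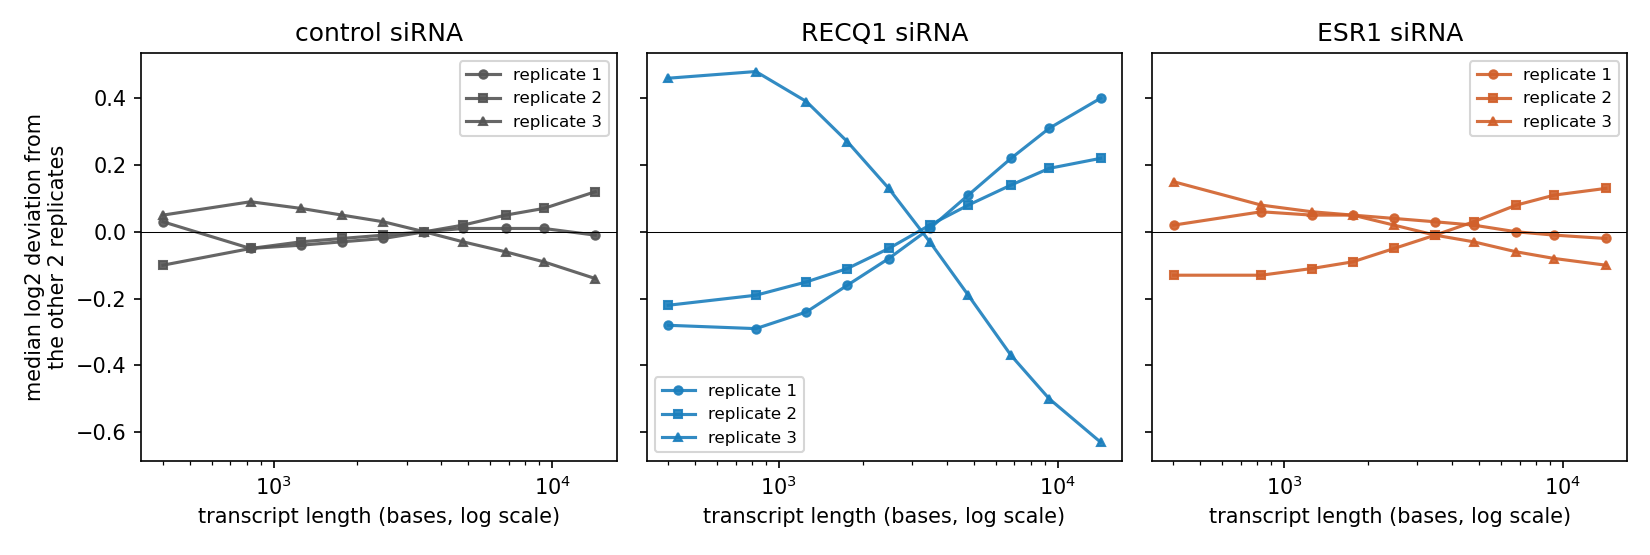
Median log2 deviation of each library from the mean of the other 2 libraries of its group (vertical axis) against transcript length in bases (horizontal log axis), in 10 length classes; each line is a library and the panels are the siRNA groups. RECQ1 siRNA replicate 3 runs from 0.46 in the shortest class to -0.63 in the longest, and the other 2 RECQ1 libraries mirror it because they are compared with it.

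Without RECQ1 siRNA replicate 3 the count of called genes was 446, of which 190 were among the 193, and 74.9% were lower. The count was smaller without control replicates 1, 2 or 3 (70, 57 and 67), without RECQ1 siRNA replicate 2 (87) and without ESR1 siRNA replicates 1 or 2 (127 and 102). Of the 33 named genes called in this comparison, 17 were called in each of the 9 fits that left out a library. UBXN11, OSCP1, TMEM238, XRCC6, SESN2, CYP51A1, TGFB2, KRT17, RND1, H19, MKNK2, CYP26B1 and KRT23 lost their call when any 1 of at least 2 of the control libraries was left out, and BRINP2, PLAC1 and MYB without control replicate 2. Some also lost it without RECQ1 or ESR1 siRNA libraries. SESN2, CYP51A1 and KRT23 were called in 1 of the 9 fits, and TMEM238, RND1 and CYP26B1 in 2.

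The 3' UTRs of the 150 genes that fell after RECQ1 siRNA and have an annotated 3' UTR held the 7-base sequence ACCAGTT in 81 genes, against 23.6 expected from genes of like UTR length, UTR base composition and expression, and CCAGTTA in 62 against 22.0. These had the highest and second highest enrichment of the 14196 sequences of that length tested (z of 13.5 and 9.7). The second is the first shifted by 1 base, both containing CCAGTT, so these sequences are not independent hits. Each occurs in RECQL mRNA, as do 2835 of the 14196. At least 1 of them was present in 101 of the 150 genes that fell and in 4 of 31 that rose, where 36.9 and 3.7 were expected. TFRC held both, DCBLD2, SLC16A1, STC1, CYP26B1, SESN2, CHPT1 and SLC39A6 held ACCAGTT, and STC2, UNG and XRCC6 held CCAGTTA. OLFML3, PLAT, PLAC1, KRT13, CAV1, TGFB2, CYP51A1 and ALDH3B2 held neither. PGR held CCAGTTA and GATA3 held ACCAGTT, and these were not called (log2 fold changes 0.03 and -0.19). The annotated ESR1 3' UTR held CCAGTTA at 2 positions.

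**Figure D3:**
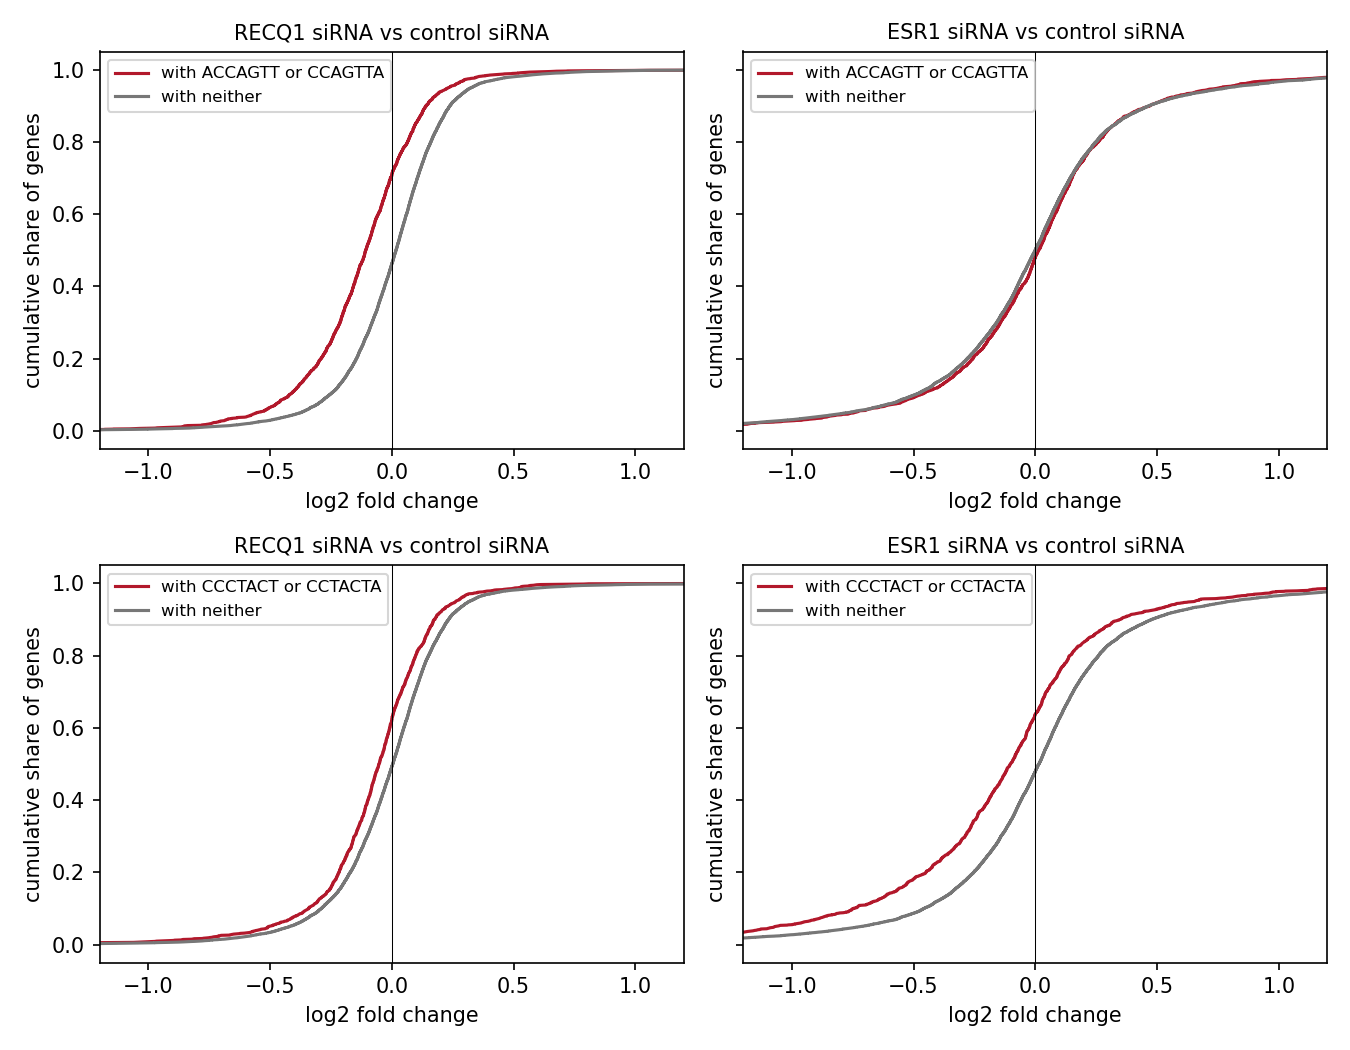
Cumulative share of tested genes (vertical axis) by log2 fold change (horizontal axis, drawn from -1.2 to 1.2) for genes whose 3' UTR holds at least 1 of a pair of 7-base sequences (red) or neither (grey); the upper panels show the pair found after RECQ1 siRNA and the lower panels the pair found after ESR1 siRNA. After RECQ1 siRNA the 2413 genes with its pair had a median of -0.11 against 0.02 for 10826 without, and after ESR1 siRNA the 1487 genes with its pair had -0.10 against 0.01 for 11752 without; these medians are not matched for UTR length.

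The comparison of ESR1 siRNA with control siRNA shows the response to this siRNA pool, which lowered the receptor mRNA, in the same cells. ESR1 mRNA fell 3.64-fold (log2 fold change -1.87 ± 0.12, SE, n = 3 per group, adjusted p = 1.3e-06), and 4275 genes passed the test, 2069 higher and 2206 lower, with 485 and 479 of them changed at least 2-fold. Known estrogen-induced genes fell together: PGR was at 4.97 CPM against 40.7, GREB1 at 209 against 1140 and TFF1 at 833 against 3460. Genes that estrogen represses rose, and 17 of 23 cholesterol synthesis genes fell. RECQL had a log2 fold change of -0.12 (SE 0.09, adjusted p = 0.391).

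Of the 52 estrogen-induced genes 46 fell, 1 rose and 5 did not pass (adjusted over the list alone, 47 lower and 1 higher), with a median log2 fold change of -1.21. Its adjusted p was 1.41e-84 by camera and 0.00117 with an estimated correlation. The log2 fold change was -3.03 for PGR (SE 0.19), -2.74 for PDZK1 (SE 0.09) and -2.52 for AREG (SE 0.09), which encodes the EGF receptor ligand amphiregulin. It was -2.45 for GREB1 (SE 0.19), -2.05 for TFF1 (SE 0.13), -1.63 for GFRA1 (SE 0.06), a receptor for glial-derived neurotrophic factor, and -0.78 for MYC (SE 0.06). P2RY2, a nucleotide receptor, rose with a log2 fold change of 0.74. CCND1, which encodes cyclin D1, had 0.07 (adjusted p = 0.499). Of the 17 estrogen-repressed genes 15 rose, 0 fell and 2 did not pass (adjusted over the list alone, 15 higher), with a median of 0.87. The adjusted p was 2e-24, and 0.00117 with an estimated correlation. PSCA had a log2 fold change of 2.68, the interleukin-1 receptor gene IL1R1 2.34 and BCAS1 1.67.

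**Figure D4:**
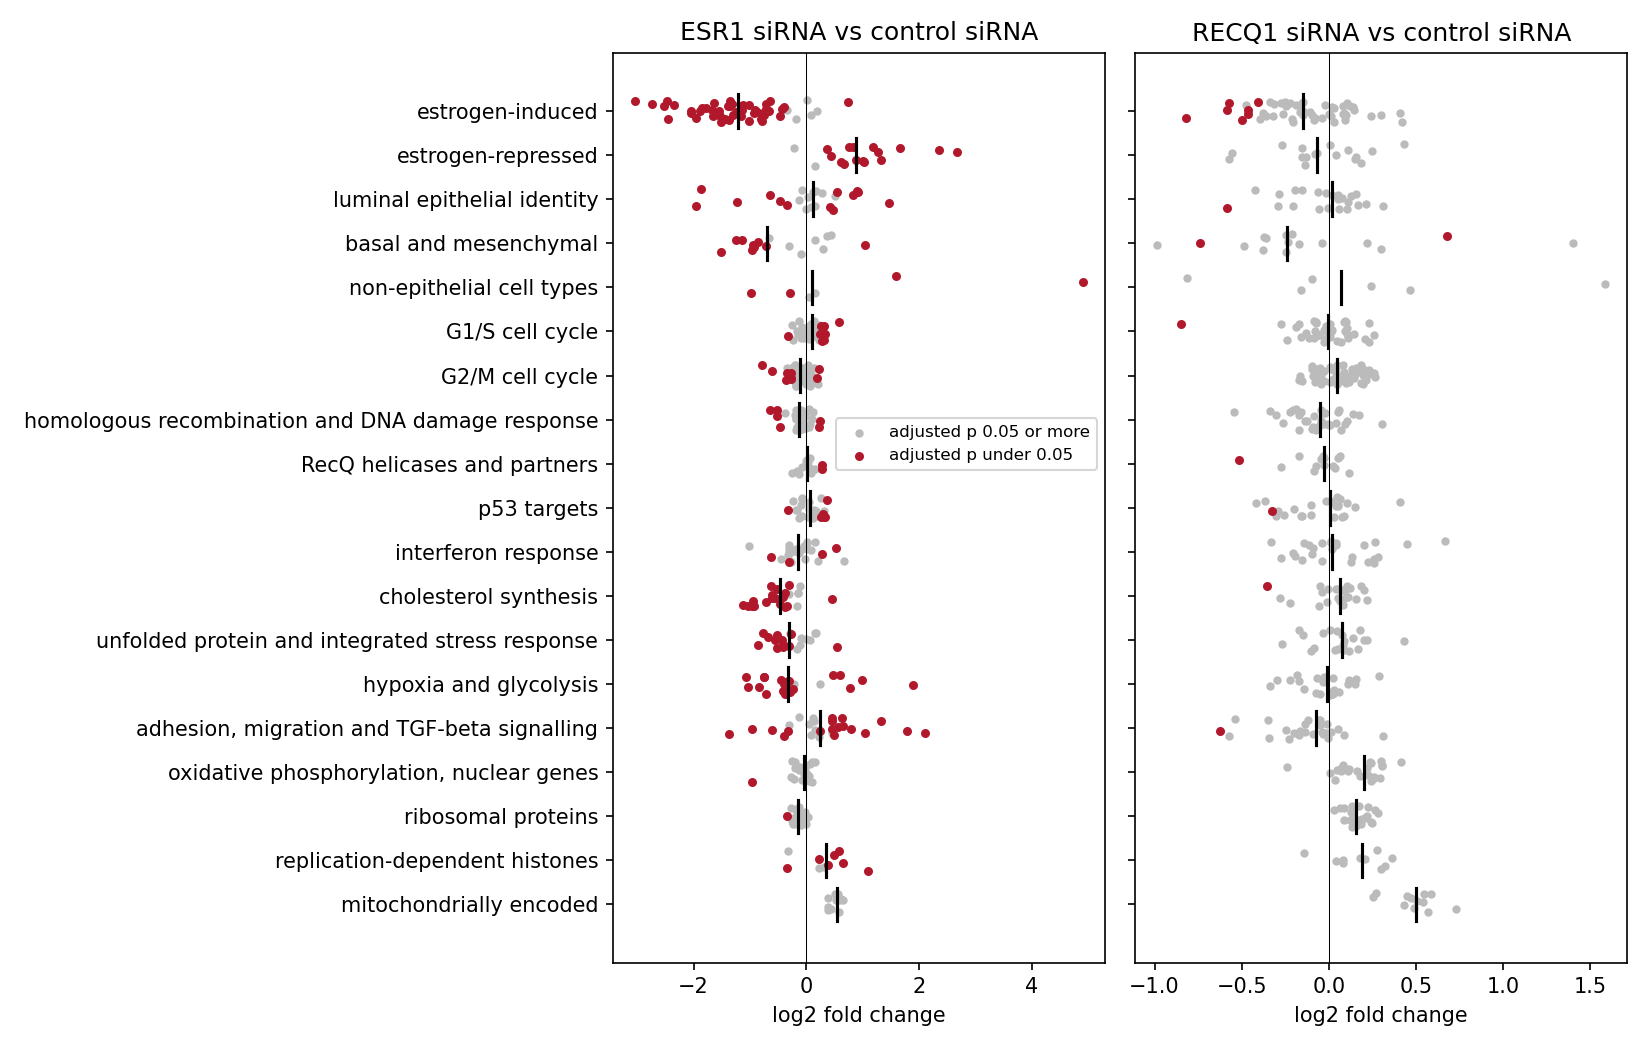
Log2 fold change of every tested member of the 19 gene lists after ESR1 siRNA (left) and RECQ1 siRNA (right), against control siRNA; each point is a gene, red where its adjusted p was under 0.05, and black bars are list medians. The 2 horizontal axes have different scales: the estrogen-induced median is -1.21 on the left and -0.15 on the right, and the point farthest to the right on the left is CDH5, which was at 0.0416 CPM in the controls.

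Among called genes at a mean of at least 5 CPM in the higher group, the largest increases after ESR1 siRNA were in KRT4, a keratin of stratified epithelia (16.2-fold, log2 fold change 4.02, SE 0.14), TINAGL1 (3.88), VGLL1, a cofactor of TEAD transcription factors (3.60), the acetylcholinesterase gene ACHE (3.49), DEPP1 (3.37), the transporter gene SLC16A5 (3.22), VAT1L (3.10) and the GABA-B receptor gene GABBR2 (2.85). The largest decreases at that level, besides PGR and PDZK1, were in the non-coding RNA LINC01016 (-3.57), PLAC1 (-3.49), RAMP3, a partner of the calcitonin-like receptor (-3.38), AGR3 (-3.33), the nuclear receptor gene NR5A2 (-2.87) and the RNA-binding protein gene RBM24 (-2.77), with SE from 0.10 to 0.17.

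Cholesterol synthesis genes fell as a group, with 17 of 23 lower, 1 higher and 5 not called (adjusted over the list alone, 19 lower and 1 higher) and a median of -0.47. The adjusted p was 9.01e-09, and 0.0123 with an estimated correlation. The latter call ended without RECQ1 siRNA replicate 3 (adjusted p = 0.063). MSMO1 (-1.04), NSDHL (-0.96) and FDFT1 (-0.95), which encodes squalene synthase, fell. DHCR24, a late enzyme of the same pathway, rose (0.45). In the basal and mesenchymal list 8 of 16 genes fell and 1 rose (adjusted over the list alone, 9 and 1). The adjusted p was 7.92e-05, and 0.103 with an estimated correlation. The hyaluronan receptor gene CD44 (-1.51), LAMC2 (-0.96) and CAV1 (-0.95) fell, and SNAI2 rose (1.03) from 0.873 to 1.80 CPM. The luminal list was split, 7 higher and 6 lower of 23 (the same counts adjusted over the list alone), with a median of 0.11 against a test direction of lower and adjusted p = 0.937. TBX3 (1.47), ELF3 (0.92) and KRT18 (0.83) rose, and MYB (-1.96) and AGR2 (-1.24) fell beside ESR1 itself. GATA3 had 0.08 (adjusted p = 0.538) and FOXA1 -0.13 (0.2).

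The unfolded protein and integrated stress list had 12 of 21 members lower and 1 higher (the same adjusted over the list alone; adjusted p = 0.00623, and 0.589 with an estimated correlation). The asparagine synthetase gene ASNS (-0.85), CRELD2 (-0.55) and PDIA4 (-0.42) fell and HERPUD1 (0.54) rose. In the hypoxia and glycolysis list 14 fell and 5 rose of 22 (adjusted over the list alone, 15 and 6; adjusted p = 0.0309, and 0.355 with an estimated correlation). The mitophagy gene BNIP3 (-1.08), the aldolase gene ALDOC (-1.04) and P4HA2 (-0.84) fell. EGLN3, a prolyl hydroxylase acting on hypoxia-inducible factor, rose (1.88) with PFKFB3 (0.78) and NDRG1 (0.48). That list was not called without RECQ1 siRNA replicate 3 (adjusted p = 0.0692), without ESR1 siRNA replicate 2 (0.103), on only the 6 libraries compared (0.0726) or with a filter of at least 1 CPM in 3 libraries (0.0501). In the adhesion, migration and TGF-beta list 13 rose and 5 fell of 28 (adjusted over the list alone, 15 and 5; adjusted p = 0.00305, and 0.589 with an estimated correlation). The integrin gene ITGB6 (1.78), the urokinase gene PLAU (1.32) and L1CAM (1.04) rose, and the laminin gene LAMA3 (-1.37), PLAUR (-0.97) and ITGA5 (-0.61) fell.

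The other lists did not pass by camera after ESR1 siRNA with all 9 libraries. Histone genes had 6 higher and 1 lower of 10 (the same adjusted over the list alone; adjusted p = 0.0511). The list passed without control replicate 3 (0.0423), RECQ1 siRNA replicate 1 (0.0297) or ESR1 siRNA replicates 1 (0.0438) or 2 (0.0246). With an estimated correlation these were 0.709, 0.587, 0.693 and 0.64, and 0.723 with all libraries. H4C8 (0.64), H2AC6 (0.57) and H3C4 (1.09) rose, and H1-0 (-0.35), which encodes a histone that is not made mainly in S phase, fell. The G1/S list had 8 higher and 1 lower of 39 (adjusted over the list alone, 7 and 1; adjusted p = 0.233), with the cyclin E2 gene CCNE2 (0.57), CDC6 (0.31) and MCM5 (0.29) higher. The G2/M list had 2 higher and 7 lower of 54 (adjusted over the list alone, 1 and 6; adjusted p = 0.191), with ANP32E (-0.79), CKS1B (-0.62) and the mitotic kinase gene PLK1 (-0.27) lower. Among 34 recombination and damage-response genes 2 rose and 4 fell (adjusted over the list alone, 0 and 4; adjusted p = 0.241). NBN, of the complex that senses double-strand breaks (-0.64), the checkpoint kinase gene CHEK2 (-0.53) and RBBP8 (-0.46) fell. RECQL5 and MSH2 (0.28 each) were the called genes of the 14 RecQ helicases and partners (adjusted over the list alone, 1 higher; adjusted p = 0.814). The p53 list had 5 higher and 1 lower of 25 (adjusted over the list alone, 7 and 1; 0.444), the interferon list 2 and 2 of 26 (2 and 1; 0.57) and the non-epithelial list 2 and 2 of 6 (2 and 2; 0.937). The endothelial cadherin gene CDH5 was at 1.41 CPM against 0.0416 and CD14 at 1.17 against 0.393. For oxidative phosphorylation 1 of 24 fell, COX6C (-0.96; adjusted over the list alone, 1; 0.489), and for ribosomal proteins 1 of 25, RPL4 (-0.34; adjusted over the list alone, 0; 0.238). The mitochondrially encoded genes had 0 of 12 called (adjusted over the list alone, 0) and a median of 0.53 (adjusted p = 0.0526). That list passed, towards higher, without ESR1 siRNA replicate 1 (0.000127), without control replicate 1 (0.000321) and with no filter on low counts (0.00457). With an estimated correlation the adjusted p was 0.543 and 0.649 without these libraries and 0.789 with all of them.

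Of the 104 named genes called after ESR1 siRNA, 87 were called in each fit that left out a library. SNAI2, CD14, PLK1, MSH2 and RPL4 were not. Without RECQ1 siRNA replicate 3, which enters this comparison through the shared estimate of the spread, 6707 genes were called in place of 4275. In the 3' UTRs of 1918 genes that fell, CCCTACT was present in 286 against 153.9 expected and CCTACTA in 186 against 102.8, the highest and second highest enrichment of 16384 sequences (z of 11.5 and 8.7). The second is the first shifted by 1 base, both containing CCTACT, so these sequences are not independent hits. Each occurs in ESR1 mRNA, as do 7894 of the 16384 sequences. Of 1000 matched random sets 0 gave as large a z for an ESR1 sequence (95th percentile 4.12), and 648 uncalled genes with CCCTACT averaged -0.04 against 0.01 in matched genes (-0.02 to 0.05). GFRA1, NSDHL and CA12 held the former, CD44 and FDFT1 the latter, and NBN and STC1 both. GABBR2, BCAS1, RND1 and TGFB2 held CCCTACT and rose. At least 1 of them was present in 394 of the 1918 genes that fell and in 144 of 1887 that rose, where 221.1 and 226.1 were expected.

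The direct comparison of RECQ1 siRNA with ESR1 siRNA tests where both knockdowns differ. It called 5221 genes, 2605 higher and 2616 lower after RECQ1 siRNA, and the estrogen response separated the groups. PGR was at 41.6 CPM after RECQ1 siRNA and 4.97 after ESR1 siRNA (log2 difference 3.07, SE 0.19, n = 3 per group, adjusted p = 1.25e-06), and TFF1 at 4090 and 833 CPM (2.30, SE 0.13). ESR1 itself was 2.72-fold higher after RECQ1 siRNA (1.44, SE 0.11, adjusted p = 6.27e-06) and RECQL 12.1-fold lower (-3.59, SE 0.11). Of the 193 genes called after RECQ1 siRNA, 159 differed between both knockdowns, beside 5221 of all 16543 tested genes. Both tests used the same RECQ1 siRNA libraries, so these calls are not independent. Of the 99 named genes called here, 79 were called in each fit that left out a library. CCND1, MSH2 and RECQL5 were not.

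Among called genes at a mean of at least 5 CPM in the higher group, the largest differences besides PGR and RECQL were in RAMP3 (3.38), AGR3 (3.01), RBM24 (3.00), the neuroendocrine transcription factor gene ASCL1 (2.92) and the bicarbonate transporter gene SLC4A10 (2.91) towards RECQ1 siRNA, and in VGLL1 (-4.81), KRT4 (-4.13), SLC16A5 (-3.78), TINAGL1 (-3.61) and GABBR2 (-3.35) towards ESR1 siRNA. Of 52 estrogen-induced genes 43 were higher and 2 lower after RECQ1 siRNA (adjusted over the list alone, 44 and 2; median 1.05; adjusted p = 1.42e-59, and 0.00165 with an estimated correlation). PKIB (2.88), AREG (2.61) and the receptor tyrosine kinase gene RET (1.69) were higher, and P2RY2 (-1.05) and CCND1 (-0.22) lower. Of 17 estrogen-repressed genes 15 were lower (the same adjusted over the list alone; median -0.86; adjusted p = 3.36e-22, and 0.00117 with an estimated correlation). Among them were IL1R1 (-2.92), PSCA (-2.81) and BCAS1 (-1.93). Of 23 cholesterol synthesis genes 17 were higher and 2 lower (adjusted over the list alone, 20 and 2; median 0.57; adjusted p = 9.78e-09, and 0.0123 with an estimated correlation). Without RECQ1 siRNA replicate 3 the list was not called with an estimated correlation (adjusted p = 0.063). NSDHL (1.05), MSMO1 (1.03) and FDFT1 (0.99) were higher and DHCR24 (-0.49) lower.

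A further 6 lists passed by camera and not with an estimated correlation. The adhesion, migration and TGF-beta list had 14 lower and 3 higher of 28 (the same adjusted over the list alone; adjusted p = 7.92e-05, and 0.429 with an estimated correlation), including ITGB6 (-2.36), PLAU (-1.86) and TGFB2 (-1.40). The unfolded protein list had 13 higher and 1 lower of 21 (adjusted over the list alone, 14 and 2; 0.0013, and adjusted p = 0.497 with an estimated correlation), including ASNS (1.01) and the serine synthesis gene PHGDH (0.73). The basal list had 7 higher and 3 lower of 16 (the same adjusted over the list alone; 0.0104, and adjusted p = 0.321), including CD44 (1.28) and KRT17 (0.99). The G2/M list had 19 higher and 1 lower of 54 (the same adjusted over the list alone; 0.0153, and adjusted p = 0.601), including CKS1B (0.84), ANP32E (0.80) and the mitotic kinase gene AURKA (0.42). Without ESR1 siRNA replicate 3 its adjusted p was 0.063. Ribosomal proteins had 8 higher of 25 (adjusted over the list alone, 13; 0.0104, and adjusted p = 0.789) and oxidative phosphorylation 6 higher and 1 lower of 24 (the same adjusted over the list alone; 0.0244, and adjusted p = 0.789). Without RECQ1 siRNA replicate 3 these had adjusted p of 0.119 and 0.156, and oxidative phosphorylation was also not called without ESR1 siRNA replicate 2 (0.0566).

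The remaining lists did not pass. Hypoxia genes had 15 higher and 5 lower of 22 (the same adjusted over the list alone; adjusted p = 0.0616), with BNIP3 (1.10) higher and EGLN3 (-2.03) lower. The list passed without ESR1 siRNA replicate 1 (0.0439) and with no filter on low counts (0.018). With an estimated correlation it did not pass without that library (0.295) or with all libraries (0.429). G1/S genes had 3 higher and 13 lower of 39 (adjusted over the list alone, 3 and 14; 0.193), with UNG (-1.08), TYMS (-0.50) and CDC6 (-0.39) lower. Recombination genes had 6 higher and 1 lower of 34 (adjusted over the list alone, 2 and 1; 0.586), with RBBP8 and CHEK2 (0.60 each) higher and CHEK1 (-0.41) lower. RecQ partners had 3 lower of 14 (the same adjusted over the list alone; 0.489): XRCC6 (-0.50), MSH2 (-0.35) and RECQL5 (-0.26). The p53 list had 3 higher and 6 lower of 25 (the same adjusted over the list alone; 0.207), the interferon list 7 and 2 of 26 (the same; 0.38), and the luminal list 5 and 9 of 23 (adjusted over the list alone, 6 and 9; 0.967). The histone list had 2 and 4 of 10 (the same; 0.455) and the non-epithelial list 1 and 1 of 6 (adjusted over the list alone, 1 and 2; 0.967, median -0.56 against a test direction of higher). The mitochondrially encoded list had 0 of 12 (0 adjusted over the list alone; 0.98, median -0.08 against a test direction of higher).

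Some genes responded to both knockdowns. Of the 193 genes called after RECQ1 siRNA 101 were also called after ESR1 siRNA, 67 in the same direction (13 higher and 54 lower) and 34 in opposite directions (8 higher after RECQ1 siRNA and lower after ESR1 siRNA, 26 the reverse). Unrelated lists of these sizes would share 25.5 and 24.4 genes. UBE2QL1 (0.88 after RECQ1 siRNA and 0.79 after ESR1 siRNA), NELL2 (0.78 and 0.51), RND1, a Rho-family GTPase gene (0.53 and 1.14), PSKH1 (0.53 and 0.52), MKNK2 (0.48 and 0.44) and the imprinted non-coding RNA H19 (0.44 and 1.87) rose in both. OLFML3 (-1.33 and -1.24), PLAT (-1.13 and -1.78), PLAC1 (-1.06 and -3.49), STC1 (-1.04 and -1.07), KRT13 (-0.82 and -0.81) and the retinoic acid-degrading enzyme gene CYP26B1 (-0.78 and -2.26) fell in both. SULF1 rose after RECQ1 siRNA and fell after ESR1 siRNA (0.86 and -0.64), and KRT23 (-0.64 and 0.85), TGFB2 (-0.62 and 0.78) and ALDH3B2 (-0.61 and 1.00) did the reverse.

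Both comparisons used the same 3 control libraries, which could not be divided, so the share of the overlap that they add is not known. In 20 simulations with unchanged groups and shared controls the log2 fold changes correlated across genes at a mean of 0.506, above the observed 0.22, while the observed covariance of 0.0442 exceeded the simulated 0.0296. Shared controls alone set that correlation when no gene changes, so its gap to the observed value does not measure a shared response. The highest simulated overlap of calls in the same direction was 0. With unchanged groups this does not show what shared controls add among genes that did change. The 67 genes became 175 without RECQ1 siRNA replicate 3, 29, 21 and 26 without control replicates 1, 2 and 3, 35 without RECQ1 siRNA replicate 2 and 40 without ESR1 siRNA replicate 2.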

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

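The fits with length or GC trends removed, and the estimated correlation with the length trend removed or without a library, were chosen after the data were seen; the other alternatives were set before. RECQL and ESR1 kept the direction and call of their own knockdown in every alternative. After RECQ1 siRNA the genes called, higher and lower were 554, 139 and 415 with DESeq2, 377, 71 and 306 with no filter, 91, 11 and 80 on only the 6 libraries compared, 623, 153 and 470 with the length trend removed, 791, 218 and 573 with the length and GC trends removed, 674, 174 and 500 with the length trend removed and 2 RECQ1 libraries, and 17, 3 and 14 at 2-fold or more. Leaving out a library gave 57 to 446, 6 to 112 and 51 to 334. After ESR1 siRNA the 6 libraries compared gave 6415 called and 3203 higher, the length and GC trends removed gave 3110 higher, the length trend removed and 2 RECQ1 libraries gave 6994, 3548 and 3446, the 2-fold threshold gave 964, 485 and 479, and leaving out a library gave 2933 to 6707, 1400 to 3350 and 1509 to 3357. In the direct comparison the 2-fold threshold gave 1070, 463 and 607. The 67 genes changed alike by both knockdowns became 179 with DESeq2, 107 with no filter, 41 on the 6 libraries compared, 243, 311 and 277 with the length trend, the length and GC trends, or the length trend and a RECQ1 library removed, 8 at 2-fold, and 21 to 175 when a library was left out. ESR1 mRNA after RECQ1 siRNA passed the threshold with DESeq2 (-0.42), no filter (-0.43), the length trend removed (-0.32), the length and GC trends removed (-0.29) and the length trend removed with 2 RECQ1 libraries (-0.29), and ranged from -0.52 to -0.28 when a library was left out, passing without RECQ1 siRNA replicate 3. The 2-fold threshold gives fewer calls by construction; for the other changes the cause was not tested. The estrogen-induced list after RECQ1 siRNA was not called with an estimated correlation (adjusted p = 0.318), alone, with the length trend removed (0.318), or without control replicates 1, 2 and 3 (0.256, 0.352 and 0.391), RECQ1 siRNA replicates 1, 2 and 3 (0.464, 0.506 and 0.425) or ESR1 siRNA replicates 1, 2 and 3 (0.308, 0.204 and 0.151). The ribosomal protein list after RECQ1 siRNA turned from higher to lower without RECQ1 siRNA replicate 3 (adjusted p = 0.644, in a range from 4.43e-07 over the libraries left out, and 0.918 with an estimated correlation) and with the length trend removed and 2 RECQ1 libraries (0.54), and the cause was not tested. For the other named genes and lists, 4338 gene values and 1315 list values kept direction and side of the threshold, 301 and 230 lost their call, 12 and 26 gained it, and 4 and 45 changed sign with no call on either side. Same-numbered replicates of different groups correlated weakly: 3 of 9 such pairs correlated above 0.1 (range -0.075 to 0.14) and 4 correlated best with their own number. Replicate 3 did so in each pair of groups (control with RECQ1 siRNA 0.13, control with ESR1 siRNA 0.085, RECQ1 with ESR1 siRNA 0.12). A weak component shared by the libraries numbered 3 therefore cannot be excluded, and its cause was not tested. A replicate block gave 258, 4520 and 5616 calls in the 3 comparisons, with 183 of the 193 genes among the 258. Depth and replicate number limit small changes: the smallest simulated change was recovered for 8% of genes in the RECQ1 siRNA comparison.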

Other observations

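The search for ESR1 sequences and the tests of transcript length, depth, swapped libraries, the slope of the estrogen response, the shift in uncalled genes and the lists without 7-base matches were chosen after the results were seen, as were the pairs of 7-base sequences looked at singly and the test on genes without them; the search of 3' UTRs for RECQL sequences and the splits of the samples were set before. Of the 150 genes with a 3' UTR that fell after RECQ1 siRNA, 49 held neither of the 2 leading sequences, and 27 such genes rose. OLFML3, PLAT, PLAC1 and KRT13 were among the 49 and fell after both knockdowns, and the estrogen-induced genes MYB, CA12 and PDZK1 were also among them.

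The 9 libraries allow 10 splits of the 6 libraries in each comparison, too few for a share under 0.05. The real split was the 1 with as many called genes in each: 193 after RECQ1 siRNA, 4275 after ESR1 siRNA and 5221 in the direct comparison, and the highest of the other splits called 0. Each other split mixes libraries of both siRNA groups, which puts real differences into the spread within groups. Their 0 calls therefore do not measure how many calls chance would give.

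RECQ1 siRNA replicate 3 lay apart from replicates 1 and 2. Its total of 39.9 M counts (M, mega) lay inside the range of the other libraries, and its RECQL level of 1.86 CPM lay with its own group, which argue against depth and against a swap with a control or ESR1 siRNA library. Its deviation followed transcript length (rho = -0.74, 49% of the variance of its deviation). Replicate 3 of the control and ESR1 siRNA groups leaned the same way less strongly (rho = -0.42 and -0.29). A candidate explanation is a length-dependent difference in RNA quality or library preparation. Nothing in the labels describes RNA quality, and no biological explanation was tested, since no group separates RECQ1 siRNA replicate 3.

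More genes fell than rose after RECQ1 siRNA, 159 against 34. A length bias of replicate 3 as the whole cause is excluded, since 75.4% of called genes were lower with the length trend removed and 74.9% without that library. The largest z of a RECQL sequence in the 3' UTRs of genes that fell was 13.5, against a 95th percentile of 4.49 and 0 of 1000 matched random sets as large, and 1456 uncalled genes with ACCAGTT averaged -0.12 against -0.06 in matched genes (-0.08 to -0.04) after RECQ1 siRNA and 0.02 against -0.01 (-0.05 to 0.04) after ESR1 siRNA. A candidate explanation is that an siRNA of the pool acted on these mRNAs through its seed, in which case UNG, XRCC6, SESN2, TFRC and the ESR1 3' UTR, with its 2 CCAGTTA sites, may have responded to the siRNA and not to loss of RECQ1, and the ESR1 sequences (z of 11.49 against a 95th percentile of 4.12) leave the same open for part of the calls after ESR1 siRNA; a microRNA of the same seed was not tested, and no second siRNA or rescue is available. Among the genes with neither sequence the largest z of other RECQL sequences was 3.91 against 4.72, and a planted pool of 4 seeds was found in a share of 0.185 of simulations, so for these 49 genes seed effects and loss of RECQ1 cannot be told apart.

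The estrogen-induced list was lower after RECQ1 siRNA by camera at the preset correlation and not with an estimated one. It also passed with fry (adjusted p = 0.00912), which does not compare its genes with other genes. For camera at the preset correlation, a length bias of replicate 3 as the whole cause is excluded. The camera adjusted p was 1.17e-05 with the length trend removed and 2.46e-05 without that library, although the median of -0.15 became -0.107 and -0.0828. Without the 13 members that hold a leading sequence the adjusted p by camera was 0.00761, with a median of -0.0827. With an estimated correlation the unadjusted p was 0.112 without these members and 0.0446 for the full list. As other seeds were planted and found in a share of 0.185 of simulations, seed effects and other causes of this shift cannot be told apart. If the lower ESR1 mRNA acted in proportion to ESR1 siRNA, effects on the 62 estrogen genes called after ESR1 siRNA would have a slope near 0.226 (95% interval of that ratio 0.106 to 0.346); the slope was 0.0501 (-0.000745 to 0.105). Its upper end was 0.0883 against 0.0859 to 0.219 without replicate 3 and 0.0966 against 0.116 to 0.222 with the length trend removed. The ratio itself was 0.153 and 0.169 in these fits. A proportionate response would also raise the estrogen-repressed genes. Of the 15 among these genes, 0 were called higher with all libraries, 1 without replicate 3 and 0 with the length trend removed. Their medians were -0.0645, -0.0887 and -0.0532. These values argue against a response in full proportion for these genes. They do not exclude it, as the intervals overlap without replicate 3 and the genes are co-regulated and not independent. Seed effects, a weaker or delayed response to lower ESR1, or an effect of RECQ1 on these genes may account for the list's shift and stay open.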
